A study of Mus musculus with 8 samples.

How the data were processed

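RNA from snap-frozen hearts (ventricles by the tissue field, whole hearts by the titles) of 8 mice, 2 in each of 4 groups, was labelled with biotin and hybridized to 1 array each, per the labels' protocols. The titles number 8 individuals, so the 2 arrays of a group come from separate animals. The deposited values are log2 expression values that the authors computed with RMA, per the submitters' processing notes; its version and the probe set definitions are not given in the sources used here. RMA corrects background, makes the arrays' intensity distributions alike and summarises probes into probe sets, so a change shared by most genes would be removed. The log2 scale was read from the values, which ran from 2.63 to 14.45. No detection calls or background levels were used, and low values are therefore close to an unmeasured floor.

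The table held 35557 rows. The platform annotation paired 21789 probe sets with 1 gene symbol, 1621 with several and 12147 with none, and only the first kind was used for genes. For 999 genes with more than 1 probe set, the one with the highest mean over the 8 arrays was taken, which left 19938 genes. Of these, 19855 had an Entrez identifier in the reference gene table of mouse assembly GRCm38.p6, which was used for the order of genes only; no genome build is named for the values, and no coordinates are given.

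Groups were taken from the titles. A linear model with 1 coefficient per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), leaving 4 residual degrees of freedom and a prior of 2.74 degrees of freedom with an SD of 0.111. The 7 contrasts were the PE effect in each genotype, their difference, the genotype effect without and with PE, and the averages of the PE and genotype effects. P values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes within a contrast, with a threshold of 0.05. Differences are on the log2 scale, PE minus untreated or S105A minus WT.

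Before the data were examined, 30 gene lists of heart, metabolic, stress and cell type marker genes were fixed. They held 621 entries, of which 569 were measured, and 29 lists had at least 5 measured genes and were tested. The test was limma's camera with a preset correlation of 0.01, adjusted over the lists, with camera with an estimated correlation and fry as alternatives; fry tests whether a list moves one way and does not compare it with other genes, and its mixed form tests for changes in either direction. Members were also adjusted over the list alone. Means of each list per array were compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest p is 0.0286, in a family of 60 tests.

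The genes named were chosen by a rule fixed before the data were examined. It took up to 12 genes per direction past the threshold with no overlap between groups. Where fewer than 5 passed, it allowed up to 5 per direction with the smallest unadjusted p and a log2 difference of at least 0.5, up to 4 members per list, and a fixed set of heart genes whatever their values. Other alternatives fixed beforehand were a filter on the 40% of genes with the lowest mean level, the mean of a gene's probe sets, all rows, a further quantile normalization, a trended and robust variance, array weights, a fit of only the 4 arrays compared, a model without interaction, an unadjusted threshold with a minimum fold, and leaving out each array in turn. The alternative without arrays 3 and 7, the counts of list members under each setting, the medians of the called lists under the alternatives run for lists and the permutation test of list means were added after seeing the data.

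The fit was tested on simulated data with the means of the real genes and independent genes whose SDs were drawn from the fitted prior, with 200 of 19938 genes changed, in 5 runs per contrast. For the PE effect in wild type, 74.9% of 2-fold changes and 96.4% of 4-fold changes were recovered; for the difference in PE effects 35.2% and 84.8%; for the averaged genotype effect 90.7% and 98.8%. The simulation holds neither correlation between genes nor a difference in spread between groups. Figures were drawn with matplotlib 3.10.9.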

Results

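Gene expression was measured in hearts of 9-week-old mice on a C57Bl6 background with an Affymetrix whole-transcript mouse gene array. The mice were wild type (WT) or carried S105A, a serine-to-alanine substitution in GATA4, a zinc-finger transcription factor of heart muscle. Both genotypes were left as controls or received PE, spelled out in the labels as pseudoephedrine, an adrenergic stimulus. It was given under the skin by osmotic pump at 100 mg per kg per day for 5 days. Each of the 4 groups held 2 arrays from separate animals, numbered 1 and 2 (WT untreated), 3 and 4 (WT PE), 5 and 6 (S105A untreated) and 7 and 8 (S105A PE). Array medians lay between 6.18 and 6.23 on the log2 scale, and 19938 genes were tested. The number of arrays limits the precision. The tissue field and the series design name the ventricle, whereas the titles name the whole heart, so the share of atrial tissue is not known. The labels do not settle whether PE stands for the drug they spell out or for another adrenergic agonist with this abbreviation. The controls are titled untreated, whereas the protocol describes saline as the alternative to PE.

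Gata4 mRNA, read by probe set 10420747, was at similar levels in the 4 groups. Its log2 value was 10.09 ± 0.06 in WT untreated, 10.04 ± 0.17 in WT PE, 10.02 ± 0.08 in S105A untreated and 10.05 ± 0.05 in S105A PE (mean ± SD, 2 arrays each). A point substitution is not visible to this probe set, so the value does not check the genotype labels. The first principal component held 69.5% of the variance. PE array 3 lay at 53.3 on it and PE array 7 at 25.1, while arrays 4 and 8 lay at -0.41 and -4.995 and the untreated arrays between -20.8 and -16.1.

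The first comparison asked which genes differed between PE and untreated hearts of wild-type mice. Myh7, the beta myosin heavy chain that is used as a marker of cardiac hypertrophy (probe set 10419934), rose from 8.41 ± 0.16 to 11.11 ± 0.32, a log2 difference of 2.70 (SE 0.17, 6.51-fold, limma adjusted p = 0.0279). It was the 1 gene of 19938 past an adjusted p of 0.05, and both PE arrays lay above both untreated arrays. Genes of injury and matrix repair had large differences that did not pass. Timp1, an inhibitor of matrix metalloproteinases, was 4.02 log2 units higher (SE 0.57, adjusted p = 0.419), the matrix glycoprotein Tnc 4.09 and Thbs1 3.02. The natriuretic peptide genes Nppa and Nppb had differences of 1.96 (SE 0.40) and 0.84 (SE 0.35), and the skeletal alpha-actin gene Acta1 one of 1.03 (SE 0.35). Postn differed by 2.92 (SE 0.59) and Col1a1 by 2.59 (SE 0.63). Myh6, the adult alpha myosin heavy chain, and the calcium pump gene Atp2a2 had differences of -0.26 (SE 0.15) and -0.24 (SE 0.14). Among the other genes with the smallest unadjusted p, none of which passed, Pttg1 differed by 2.16, Rrad by 0.84, Clec4n by 1.38 and Hyi by 0.87. On the lower side were Alas2, the erythroid enzyme of heme synthesis, at -1.92, Tent5c at -1.43 and Amacr at -0.73. At an unadjusted p under 0.01 with at least a 1.5-fold difference, 95 genes were higher and 68 lower.

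Myh7 lost its call in wild type when array 1, 2, 5, 6, 7 or 8 was left out, with adjusted p values of 0.275, 0.248, 0.137, 0.137, 0.138 and 0.138, and kept it without array 3 (0.00517) or 4 (0.00167). It was also lost with all rows of the table tested (0.0824) and in a fit of only the 4 WT arrays (0.533). Without array 3 or 4, the difference between these 2 arrays no longer entered the estimated spread, which bears on the counts that follow. The number of genes past the threshold was 3541 without array 4, 4 without array 3, 1 without array 5 or 6 (a gene other than Myh7), 0 without array 1, 2, 7 or 8, and 58 without arrays 3 and 7, an alternative chosen after seeing the data.

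In S105A hearts, the same comparison gave 0 genes past an adjusted p of 0.05 by limma, and 1169 genes (5.86%) at an unadjusted p under 0.05. Myh7 again had the smallest p, with a log2 difference of 1.91 (SE 0.17, 3.75-fold, adjusted p = 0.271). Tnc differed by 4.50 (SE 0.65, adjusted p = 0.765), Timp1 by 3.19, Postn by 3.20 (SE 0.59), Fn1 by 2.68 and Col1a1 by 2.17 (SE 0.63). Nppa was 6.06-fold higher (log2 SE 0.40), Nppb had a difference of 1.01 (SE 0.35), Ankrd1 one of 0.69 and Acta1 one of 0.50 (SE 0.35). Pi16 differed by 1.00, the potassium channel subunit gene Kcne1 by 0.86 and the myeloid receptor gene Cd300ld by 1.09. Lrp2bp lay lower, at -0.65, and Alas2 at -0.69. Myh6 (-0.07, SE 0.15) and Atp2a2 (-0.08, SE 0.14) stayed near 0, and both turned slightly positive after a further quantile normalization, to 0.005 and 0.05. At an unadjusted p under 0.01 with at least a 1.5-fold difference, 53 genes were higher and 9 lower. The count at the adjusted threshold was 30 without arrays 3 and 7, and 1 without array 3 or array 4.

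**Figure D1:**
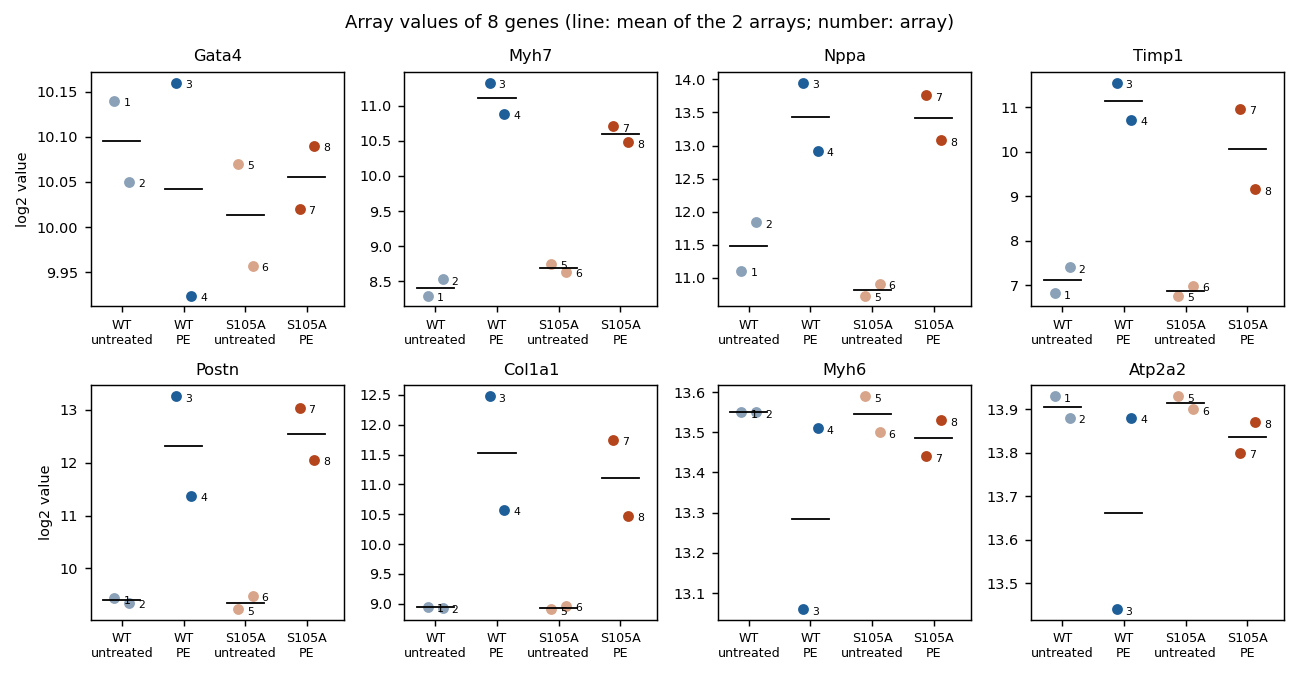
Log2 array values (y axis) of 8 genes in the 4 groups (x axis); each point is 1 array, labelled with its number, and each line is the mean of the 2 arrays. Myh7 in the PE groups averaged 11.11 (WT) and 10.60 (S105A) against 8.41 and 8.69 without PE, and array 3 lay above array 4 for Timp1, Postn and Col1a1.

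Averaged over the genotypes, PE raised Myh7 by 2.30 log2 units (SE 0.12, 4.94-fold, limma adjusted p = 0.00808), and all 4 PE arrays lay above all 4 untreated arrays. No other gene passed. The call was lost without array 1, 2, 5, 6 or 7, where the adjusted p was 0.144, 0.110, 0.0854, 0.197 and 0.0576, and kept without array 3 (0.00181), 4 (0.000928) or 8 (0.0400). Without arrays 3 and 7, 127 genes were higher and 10 lower, and the count was 4137 without array 4, 5 without array 3, 4 without array 8 and 0 without array 1, 2, 5, 6 or 7. A group left with a lone array adds nothing to the estimated spread. Without arrays 3 and 7 the spread came from the untreated arrays alone, so these counts do not measure the PE response alone. At an unadjusted p under 0.01 with at least a 1.5-fold difference, 248 genes were higher and 19 lower. Clec4n (1.31), Ankrd1 (0.72) and Kcne1 (0.69) were among the higher genes that did not pass at the adjusted threshold, and Tent5c (-0.96), Alas2 (-1.30), Lrp2bp (-0.64) and Nt5c1a (-0.51) among the lower.

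Genes of the extracellular matrix made up the broadest group. All 42 measured members were higher with PE, with a median of 1.51, and 40 of them passed when adjusted over the list alone, against 0 over all genes tested. Tnc rose by 4.30, Timp1 by 3.605, Postn by 3.06 and Thbs1 by 2.65 log2 units (limma adjusted p = 0.00121, 0.00121, 0.00262 and 0.00353, adjusted over the list alone). In the separate genotypes 27 members passed over the list alone in WT and 12 in S105A. The list passed camera with its preset correlation (adjusted p = 2.24e-28), which it did not with its own correlation of genes (adjusted p = 0.539 with an estimated correlation). The median was 0.75 without arrays 3 and 7. The count of 40 was 26 without array 1, 2 or 5 and 24 without array 7. In WT it was 0 without array 1 or 2, 6 without array 5 or 6, 8 without array 3 and 42 without array 4. In S105A it was 0 without array 5 or 6, 2 without array 7, 3 without array 1 or 2, 25 without array 8 and 40 without array 3 or 4. Without the 40% of genes with the lowest level the counts were 25 in WT and 3 in S105A, and without arrays 3 and 7 they were 32 and 36, so the order of the genotypes turned. The effects of PE in WT and in S105A, which share no arrays, correlated over the 42 members (Pearson r = 0.932 across genes, Spearman rho = 0.930) and over all 19938 genes (r = 0.767, rho = 0.561), although genes are not independent replicates. Within the PE arrays, the difference of array 3 from array 4 correlated with that of array 7 from array 8 over all genes (r = 0.665, rho = 0.514). What sets arrays 3 and 7 apart enters both PE effects, so these correlations do not measure a shared PE effect alone.

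Macrophage markers were higher as well. Of 20 measured, 19 passed when adjusted over the list alone and 0 over all genes, with a median of 0.81 that was 0.51 without arrays 3 and 7. Ctss, a lysosomal protease of myeloid cells, rose by 1.40, Lgals3 by 1.30, Adgre1 by 1.23 and Cd68 by 1.07. Of 16 hypertrophy markers, 12 passed over the list alone, Myh7 being the 1 that also passed over all genes, with Nppa at 2.28, Rcan1 at 1.01 and Ankrd1 at 0.72. Cell cycle genes had a median of 0.72, and 14 of 30 passed when adjusted over the list alone and 0 over all genes. Among these were Mki67 (1.65), Top2a (1.58), Kif20a (0.86) and Ube2c (0.86), which act in dividing cells. Fibroblast markers had 8 of 16 past the threshold when adjusted over the list alone and 0 over all genes, led by the microfibril genes Mfap5 (2.13) and Mfap4 (1.87). All 4 lists passed camera with the preset correlation, and none did with camera and an estimated correlation (adjusted p = 0.539 with an estimated correlation for each). Leaving out 1 array at a time gave 15 to 19 macrophage markers, 5 to 13 hypertrophy markers, 0 to 25 cell cycle genes and 1 to 11 fibroblast markers. The cell cycle median was 0.45 without array 7 and 0.31 without arrays 3 and 7. The cell cycle count was 0 without array 1, 2, 3, 5, 6 or 7, 22 without array 4 and 25 without array 8. The hypertrophy count was 5 without array 1, 5 or 7 and 7 without array 2, and the fibroblast count was 1 without array 1, 6 or 7, 2 without array 5 and 4 without array 2.

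Energy metabolism lists lay on the lower side. All 42 oxidative phosphorylation genes had negative differences with PE (median -0.32), among them Ndufa1 (-0.61) and Ndufa5 (-0.66) of complex I, and 0 passed over the list alone or over all genes. Of 31 fatty acid oxidation genes, 29 were lower (median -0.53), with the nuclear receptor gene Ppara at -0.77 and the carnitine carrier gene Slc25a20 at -0.64, and again 0 passed when adjusted over the list alone. The preset camera adjusted p was 2.39e-10 and 3.09e-06 for the 2 lists; it was not kept for either (adjusted p = 0.568 and adjusted p = 0.617 with an estimated correlation). The medians of the 2 lists were -0.14 and -0.22 without array 3 and -0.48 and -0.83 without array 4. The mean of the oxidative phosphorylation list was 11.48 in array 3, 12.14 in array 4, 11.98 in array 7 and 12.14 in array 8, against 12.19 to 12.30 in the untreated arrays. Endothelial markers, including Kdr (-0.42) and Flt1 (-0.34), had a median of -0.15 and 0 members past the threshold over the list alone (preset camera adjusted p = 0.00231, adjusted p = 0.568 with an estimated correlation). Cardiac ion channel genes had a median of -0.43, with Kcnv2 at -1.03, while Kcne1 rose by 0.69 as the 1 of 19 past the threshold adjusted over the list alone (adjusted p = 0.617 with an estimated correlation for the list).

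**Figure D2:**
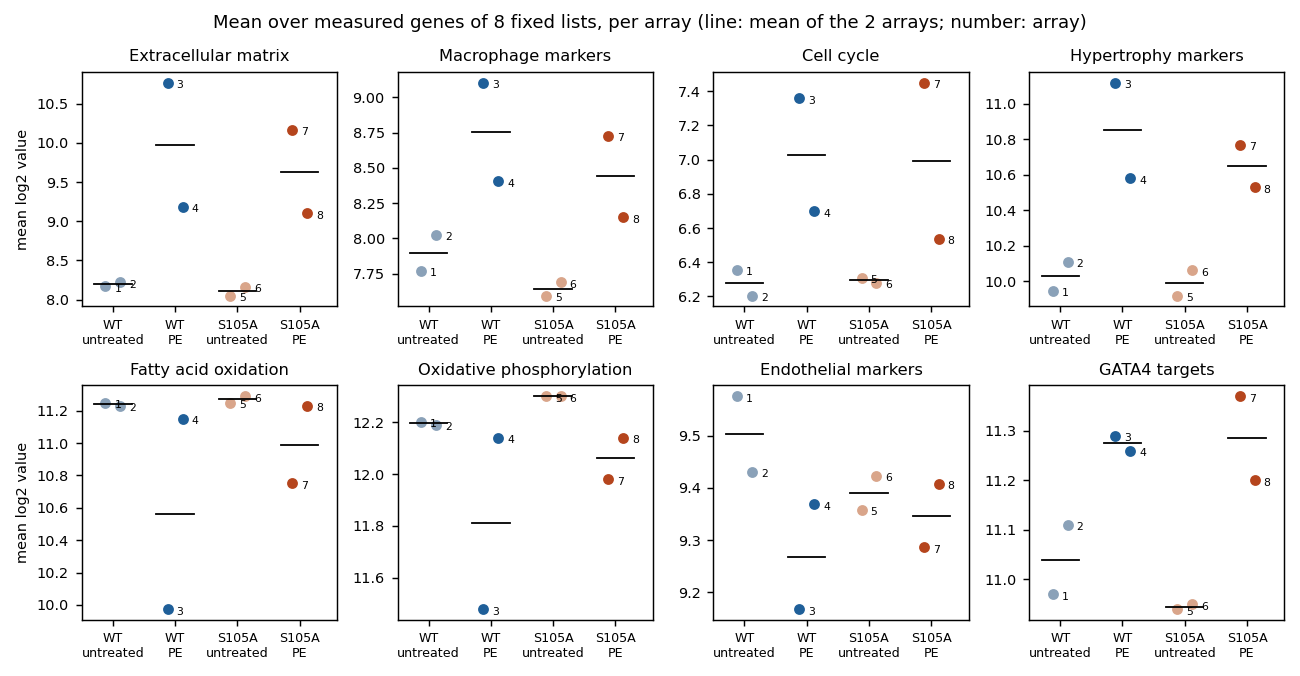
Mean log2 value over the measured genes of 8 lists (y axis) in each array, by group (x axis); points are arrays, labelled with their number, and lines are means of the 2 arrays. The extracellular matrix mean was 10.77 in array 3, 9.18 in array 4, 10.17 in array 7 and 9.10 in array 8, and between 8.05 and 8.22 in the untreated arrays.

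The difference between genotypes in the PE effect was tested directly as an interaction. By limma 0 genes passed an adjusted p of 0.05, and 483 (2.42%) had an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 63 genes, fewer than the 199.4 expected by chance. Pttg1, which encodes securin, had the smallest p, with a difference of -2.80 (SE 0.26, adjusted p = 0.336). It averaged 7.67 in WT untreated, 9.82 in WT PE, 10.32 in S105A untreated and 9.68 in S105A PE, so that the low level was that of the WT untreated arrays. Ublcp1 (-1.14), Bod1 (-0.96) and Rrad (-0.72) had differences of the same sign, and Fabp7 (1.02), Tent5c (0.94) and Amacr (0.69) of the opposite sign. Pi16 (0.87) was the 1 of 16 fibroblast markers past the threshold when adjusted over the list alone, and 0 passed over all genes (limma adjusted p = 0.0216 over the list, adjusted p = 0.769 with an estimated correlation for the list). The fibroblast list passed camera with the preset correlation (adjusted p = 0.0151), a call lost without array 2, 4, 6 or 7 (0.0794, 0.479, 0.0501 and 0.269) and with the filter on low levels (0.0555). For Myh7 the PE effect in S105A minus that in WT was -0.80 (SE 0.24, adjusted p = 1.00). Fatty acid oxidation genes had a median difference of 0.39, with Ppara at 0.84 and Acot2 at 0.95, and 0 of 31 members passed when adjusted over the list alone or over all genes (preset camera adjusted p = 0.000648, adjusted p = 0.788 with an estimated correlation). Pttg1 passed without array 3 (adjusted p = 0.0158), without array 4 (0.0205) and without arrays 3 and 7 (0.00432). The count of genes was 7 without array 4 and 1 without array 3. In total 9 lists passed camera with the preset correlation and 14 without array 4. Without array 3, 4 of the 9 were lost and 2 were called in the opposite direction, namely fatty acid oxidation genes (median -0.19, preset camera adjusted p = 0.00422) and oxidative phosphorylation genes (median -0.15 in place of 0.13). The fatty acid oxidation median was 0.18 without array 8, where the call was lost (0.168), 0.59 without array 7 and 1.00 without array 4. Without arrays 3 and 7 the fatty acid oxidation call was lost (median 0.04, 0.594) and the oxidative phosphorylation list was called in the opposite direction (median -0.08).

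Without PE, S105A and WT hearts differed in 0 genes at an adjusted p of 0.05 by limma, with 989 genes (4.96%) at an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 167 genes, against 199.4 expected by chance. Pttg1 came closest, 2.65 log2 units higher in S105A (SE 0.18, 6.28-fold, adjusted p = 0.05003), and it passed with the mean of a gene's probe sets (0.0499), with a trended and robust variance (0.0395) and with array weights (0.000778). Tmem37 was 1.00 higher (SE 0.09, adjusted p = 0.120), the spliceosome gene Snrpe 0.85, Ublcp1 1.05 and Akr1e1 0.50. Lower in S105A, without passing, were Lgr6 (-2.03), Fabp7 (-0.94), Fstl4 (-0.80), Entpd4 (-0.79) and Ankrd49 (-0.56). Gata4 itself had a group mean of 10.02 in S105A untreated and 10.09 in WT untreated. Macrophage markers had a median of -0.24 (Ctss -0.50, C1qb -0.48) and 0 of 20 passed when adjusted over the list alone or over all genes (preset camera adjusted p = 0.0284, adjusted p = 0.962 with an estimated correlation). Cacnb2, a calcium channel subunit gene, was 0.42 higher, and Pi16 had a difference of -0.57; each was the 1 member of its list, calcium handling and fibroblast markers, past the threshold when adjusted over the list alone, and neither passed over all genes (limma adjusted p = 0.0188 and 0.0345 over the lists, adjusted p = 0.962 with an estimated correlation for both). The macrophage call was lost without array 2 or 5 (preset camera adjusted p = 0.346 and 0.217) and with the filter on low levels (0.0999), and the number of lists past camera went from 4 to 2, 0 and 0. Leaving out array 3 or 4 brought 3 genes past the threshold, among them Pttg1 (adjusted p = 0.00110), and leaving out arrays 3 and 7 brought 4.

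With PE, S105A and WT hearts again differed in 0 genes at an adjusted p of 0.05 by limma, with 535 (2.68%) at an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 83 genes, against 199.4 expected by chance. Tmem37 was 1.04 higher in S105A (SE 0.09, adjusted p = 0.184), Crnde 1.06, Snrpe 0.80 and Akr1e1 0.52. Ogdhl, a relative of the oxoglutarate dehydrogenase subunit, was at -2.90 (SE 0.49), Ocel1 at -1.36, 3110040M04Rik at -0.78, Entpd4 at -0.69 and Cep126 at -0.68. Lcn2, an acute phase gene of the lipocalin family, was 1 of 22 inflammatory genes past the threshold when adjusted over the list alone (limma adjusted p = 0.0343) and not over all genes, at -2.26, while Serpina3n was at -1.43. All 42 oxidative phosphorylation genes were higher in S105A (median 0.26, Ndufb10 0.49) and 29 of 31 fatty acid oxidation genes were (median 0.39, Fabp3 0.30). In both lists 0 members passed over the list alone (adjusted p = 0.665 with an estimated correlation for each), and the inflammatory list had adjusted p = 0.665 with an estimated correlation. All 20 macrophage markers were lower (median -0.26, Lgals3 -1.07), also with 0 past the threshold and with adjusted p = 0.665 with an estimated correlation. The extracellular matrix list was called lower in S105A by camera with the preset correlation. Its mean was 9.64 in S105A PE and 9.98 in WT PE, where array 4 was at 9.18. Without array 3 the macrophage call was lost with a median of 0.09 (preset camera adjusted p = 0.543), and without array 8 with one of 0.02 (0.646). Both metabolic lists turned without array 3 and were called lower in S105A, with medians of -0.07 for oxidative phosphorylation genes (0.0101) and -0.15 for fatty acid oxidation genes (0.00272). Without array 4 the medians were 0.61, 1.00 and -0.66 for the oxidative phosphorylation, fatty acid oxidation and macrophage lists. Without array 8 the metabolic medians were 0.17 and 0.22, and without array 7 the fatty acid oxidation median was 0.63 and the macrophage median -0.58. The inflammatory call was lost without array 4 or 8 (0.874 and 0.264) and with the filter on low levels (0.123), and the oxidative phosphorylation call without arrays 3 and 7 (median 0.002, 0.758). Of the 14 lists past the preset camera threshold, 2 kept their direction and call without array 3, and 3 were called in the opposite direction, the third being extracellular matrix genes; without array 8 these numbers were 6 and 1. The number of genes past the threshold was 711 without array 4, 4 without array 3 and 5 without arrays 3 and 7.

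Averaged over the treatments, Tmem37, a gamma-like calcium channel subunit (probe set 10357239), was 1.02 log2 units higher in S105A (SE 0.06, 2.03-fold, limma adjusted p = 0.0218). All 4 S105A arrays lay above all 4 WT arrays, with group means of 7.66 and 7.51 against 6.66 and 6.47. It was the 1 gene past the threshold. Next by unadjusted p, without passing, came Entpd4 (-0.74), Snrpe (0.83), Akr1e1 (0.51), 3110040M04Rik (-0.60), Pttg1 (1.25), Lgr6 (-1.72), Ogdhl (-3.09), Crnde (0.90), Fstl4 (-0.62) and Ndrg4 (1.44). At an unadjusted p under 0.01 with at least a 1.5-fold difference, 19 genes were higher and 15 lower. Without the minimum fold, 184 genes had an unadjusted p under 0.01, against 199.4 expected by chance. Camera with the preset correlation called 6 lists, including extracellular matrix, inflammatory, fatty acid oxidation and circadian clock genes. The means of these 4 lists differed by -0.21, -0.25, 0.23 and 0.14. All 4 calls were lost without array 8. The matrix call was also lost without array 1, 2 or 5, the inflammatory call without array 2, 4 or 5, and both with the filter on low levels. The clock call was also lost without array 1, 3, 5 or 7, and the fatty acid oxidation call without array 3. Without array 3, 1 of the 6 lists was called in the opposite direction. Also called were macrophage markers, which were lower (20 of 20, median -0.28, Ctss -0.50, Lgals3 -0.63), and oxidative phosphorylation genes, which were higher (41 of 42, median 0.16, Ndufa1 0.38). In these last 2 lists, 0 members passed over the list alone or over all genes, and both had adjusted p = 0.940 with an estimated correlation. The preset camera call was lost without array 3 for both, with medians of -0.06 for macrophage markers (0.182) and -0.002 for oxidative phosphorylation genes (0.480), and without array 8 for macrophage markers (median -0.14, 0.148). Adjusted over the list alone, and not over all genes, 1 member passed in each of 3 further lists: Cacnb2 (0.28), Lcn2 (-1.45, glucocorticoid and muscle atrophy genes) and Cdh19 (-0.26, nerve and glia markers), with limma adjusted p = 0.0267, 0.0456 and 0.0365 (adjusted p = 0.940 with an estimated correlation for each list). The Tmem37 call was lost without array 1, 2, 5, 6, 7 or 8 (adjusted p = 0.192, 0.138, 0.220, 0.408, 0.229 and 0.144) and with all rows of the table tested (0.0673), and 225 genes passed without array 4, 14 without array 3 and 22 without arrays 3 and 7.

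**Figure D3:**
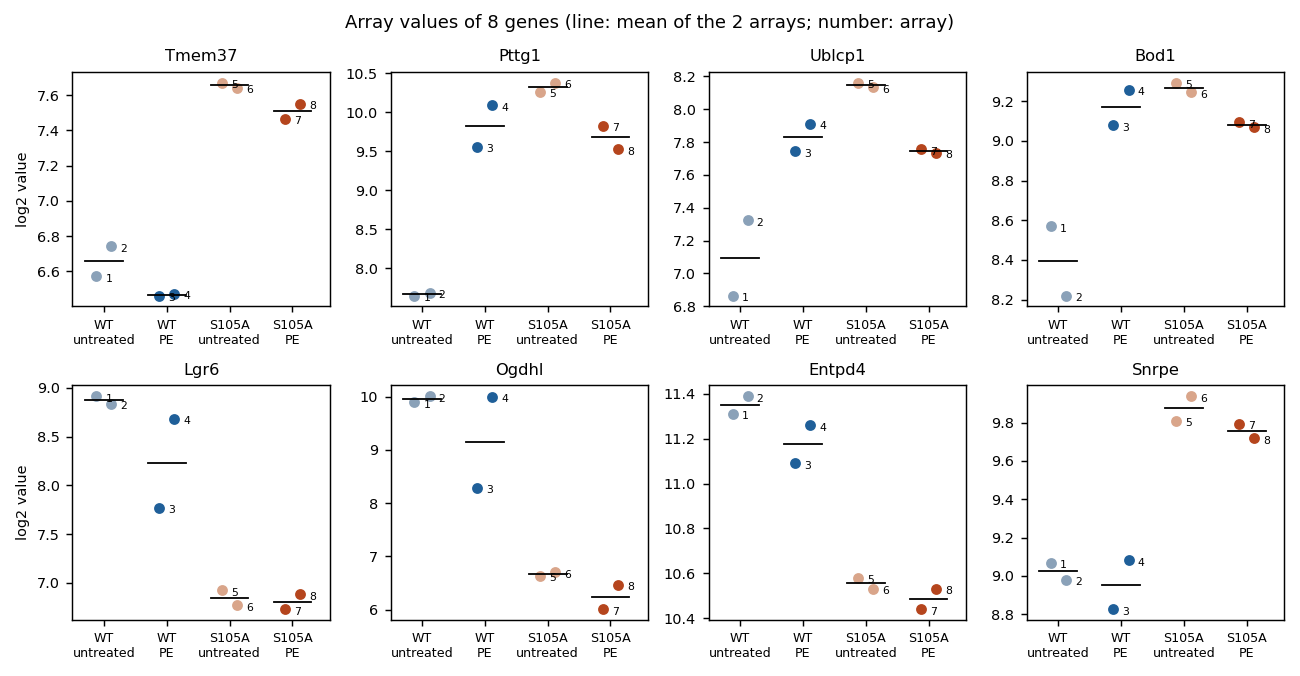
Log2 array values (y axis) of 8 genes in the 4 groups (x axis); each point is 1 array, labelled with its number, and each line is the mean of the 2 arrays. Tmem37 averaged 7.66 and 7.51 in the S105A groups and 6.66 and 6.47 in the WT groups, and Pttg1 averaged 7.67 in WT untreated and between 9.68 and 10.32 elsewhere.

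The fixed list of GATA4 target genes had 19 measured members. With PE its median was -0.04 in WT and 0.05 in S105A, and Nppa and Myh7 were the 2 members past the threshold adjusted over the list alone in either genotype. Over all genes Myh7 passed in WT and neither in S105A, with a difference between genotypes of -0.80 for Myh7 (adjusted p = 1.00) and 0.64 for Nppa. The list passed camera in S105A alone (preset adjusted p = 0.00278, adjusted p = 0.397 with an estimated correlation), a call lost without array 7 (0.0564) or arrays 3 and 7 (0.0901), and the difference between genotypes did not pass (0.0974). Between genotypes, averaged over treatments, its median was -0.03, the members ranged from -0.33 to 0.19, and 0 passed when adjusted over the list alone or over all genes (adjusted p = 0.940 with an estimated correlation).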

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

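The tests of arrays 3 and 7, of neighbouring genes and of GATA4 targets were chosen only after the results were seen; the counts over splits of the arrays were fixed before those counts were seen. The PE effect differed between genotypes for 9 lists by camera with the preset correlation, and for 0 of them otherwise (lowest adjusted p = 0.636 with an estimated correlation). The adjusted p was 0.000562 for endothelial markers and for cardiac transcription factor genes, 0.000648 for fatty acid oxidation genes, 0.00105 for cardiac ion channel genes, 0.00179 for glucocorticoid and muscle atrophy genes, 0.00302 for oxidative phosphorylation genes, 0.00330 for interferon response genes, 0.00664 for unfolded protein response genes and 0.0151 for fibroblast markers. All 9 medians were above 0, but the calls depended on several arrays. Over the omissions of 1 array, cardiac transcription factor genes alone stayed called throughout. Without array 8, 3 lists were lost, and without arrays 3 and 7, 4 were lost and 1 was called in the opposite direction. Without array 3, 3 lists stayed called in that direction, 4 were lost, and 2 were called in the opposite one, oxidative phosphorylation genes (median 0.13 with all arrays, -0.15 without array 3) and fatty acid oxidation genes (0.39 and -0.19). Named members were Kcna5 (1.20), Myocd (0.50), Kdr (0.46) and Errfi1 (1.23), with Lcn2 at -1.63, none of them past an adjusted p of 0.05.

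Camera with the preset correlation called lists in every split of the 8 arrays into 4 and 4. For PE against untreated the real split gave 15 lists in a fit of 2 groups, the highest of the other splits gave 14, and 1 of the 35 splits gave as many, the real one. For S105A against WT the real split gave 3 lists and 35 of the 35 splits gave at least as many, up to 15 for the PE split, so chance was not excluded for the genotype lists. For genes past an adjusted p of 0.05, PE against untreated gave 7 and the highest other split 3, which was the genotype split; 1 of 35 splits reached the real count. At an unadjusted p under 0.01 with a 1.5-fold difference it gave 423 genes against at most 120 in other splits, again 1 of 35. For each PE count the share lay under the 0.05 set beforehand. It is the smallest share that 35 splits can give, so these counts alone cannot exclude chance. S105A against WT gave 3 genes at the adjusted threshold, reached by 2 of 35 splits (highest other 7), and 29 at the other threshold, reached by 3 of 35 (highest other 423). These shares do not exclude chance for the genotype counts. They include the PE split, which holds the PE effect itself, and at the adjusted threshold every split other than these 2 gave 0 genes. The splits with more genes, PE against untreated and a split placing arrays 1, 5, 6 and 8 together, point to the structure given by the PE arrays.

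PE arrays 3 and 7 stood apart from arrays 4 and 8 of their groups. Poor RNA or array quality of arrays 3 and 7 as the only source of this was argued against by 2 correlations. The difference of array 3 from array 4 followed the PE effect in S105A computed without array 7 (Pearson r = 0.444 across genes). That of array 7 from array 8 followed the WT effect without array 3 (r = 0.466). A quality difference added to a PE response could give such values too, so a part played by quality stays open. Deviations of genes from their median over the arrays had an interquartile range of 0.251 in array 3 and 0.187 in array 7. In the other arrays it was 0.095 to 0.138. With a larger share of all non-muscle tissue alike, fibroblast and endothelial markers would rise together. Fibroblast markers exceeded endothelial markers by a median of 0.42 in array 3 (95% interval 0.08 to 1.51, bootstrap over marker genes) and 0.39 in array 7 (0.10 to 0.98). The endothelial medians were -0.20 and -0.07. These values argue against it for these arrays only, because the intervals measure spread among marker genes and not between animals. A larger share of macrophages, whose markers had medians of 0.70 and 0.59, and of fibroblasts stays open. The same correlations (smaller value 0.444) are consistent with a stronger response to PE in these animals, as a hypothesis. A quality or handling difference graded over all 4 PE arrays stays open, because the design gives no array on which to separate it from PE.

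Genes past an unadjusted threshold for a difference between genotypes lay near one another more often than random sets. Of the 34 genes past an unadjusted p under 0.01 with a 1.5-fold difference, 8 had another within 20 measured genes, against a median of 2 and a 95th percentile of 6 in 10000 random sets (permutation p = 0.0140); among as many genes ranked for the PE effect, 2 did (permutation p = 0.684). The pairs were Ctse with Pm20d1, Lgr6 with Csrp1, Ocel1 with B3gnt3 and Irx3 with Crnde, which may mark stretches of DNA from another strain at several loci, although within 10 genes the excess was not past the 95th percentile (4 genes, permutation p = 0.101; within 50 genes 16, permutation p = 0.0002) and neighbours can also share regulation. In the separate genotype comparisons, 10 of 39 genes had a neighbour without PE and 8 of 28 with PE (permutation p = 0.0088 and 0.0042). For the averaged PE effect at the same threshold, 126 of 267 genes had one (permutation p = 0.0599). Random sets of that size had a median of 110 and a 95th percentile of 126, so some nearness was not ruled out for PE genes either. The 200 genes around Gata4 held 1 of the 34, Entpd4 (Fisher's exact test, two-sided, p = 0.291, odds ratio 2.99, 95% interval 0.07 to 18.0). This test neither showed nor excluded DNA of another strain beside Gata4. Without PE, Entpd4 (-0.79) lay in 1 stretch with Stc1 (-0.65) and Slc25a37 (-0.67), all lower in S105A. The test around Gata4 was not run on that comparison. Altered GATA4 activity on its targets stays open too: 15 of 19 target genes had 95% intervals within 1.5-fold, and 0 had an unadjusted p under 0.05 by limma.

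The genes past the same unadjusted threshold for a difference between genotypes in the PE effect showed a similar arrangement. Of 29 genes, 5 had another within 20 measured genes (95th percentile of random sets 4, permutation p = 0.0433), namely Pttg1, Ccnjl and Ublcp1 in one stretch and Gpr75 and Bod1 in another. For Pttg1, Ublcp1 and Bod1 the WT untreated arrays were the low ones, with Pttg1 at 7.65 and 7.68 against at least 9.52 elsewhere. A candidate explanation is loci that vary among the wild-type animals, so that PE would not be needed for the difference; genotyping of the individual animals would test it. An effect of PE that truly differs with the S105A genotype at these genes stays open.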

How the results depend on the processing

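Leaving out PE arrays 3 and 7 and counting list members under each setting were chosen after seeing the data; the other alternatives were fixed beforehand, and apart from what fewer arrays or genes bring, the cause was not tested. For the 7 gene counts in the order PE in WT, PE in S105A, their difference, genotype without PE, genotype with PE, PE averaged and genotype averaged, the unadjusted threshold with a minimum fold gave 163, 62, 29, 39, 28, 267 and 34 genes, and leaving out arrays 3 and 7 gave 58, 30, 1, 4, 5, 137 and 22. Array weights gave 2 for PE in WT, 1 for PE in S105A, 6 for genotype without PE and 6 averaged. All rows gave 0 for PE in WT and 0 for genotype averaged. The mean of probe sets gave 1 and the trended and robust variance 1 for genotype without PE. Only the 4 arrays compared gave 0 for PE in WT and 4 for genotype without PE. The model without interaction gave 4 for genotype averaged. Leaving out 1 array at a time gave 0 to 3541, 0 to 1, 0 to 7, 0 to 3, 0 to 711, 0 to 4137 and 0 to 225 genes. The lone array left in a group was assumed to vary like the others and added nothing to the estimated spread. The spread therefore changed in these fits along with the differences. Without arrays 3 and 7 it came from the untreated arrays alone.

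Camera with an estimated correlation and fry for a shared direction gave 0 lists in all 7 comparisons. The mixed form of fry called hypertrophy markers and GATA4 targets, which share Nppa and Myh7, for PE in WT (adjusted p = 0.0153 for both) and with PE averaged (0.00534 for both), and no list in the other 5 comparisons. The low-level filter gave 0 lists for genotype without PE and 7 with PE, and leaving out arrays 3 and 7 gave 8 and 9. Leaving out 1 array at a time gave 13 to 16, 11 to 14, 8 to 14, 0 to 5, 10 to 14, 13 to 17 and 3 to 10 lists. With PE averaged, it gave 24 to 42 matrix, 15 to 19 macrophage, 0 to 25 cell cycle, 5 to 13 hypertrophy and 1 to 11 fibroblast members past the threshold over the list alone. Under a further quantile normalization the PE difference in S105A turned to 0.00497 for Myh6 and 0.0456 for Atp2a2. For Gata4 the PE difference ran from -0.167 without array 3 to 0.0711 without array 4 in WT, and from -0.0210 without array 6 to 0.0966 without array 5 in S105A. Of the other settings for named genes, 2270 kept direction and side of the threshold, 271 gained a call and 20 lost one. The gained calls include those at the laxer unadjusted threshold with a minimum fold and those from fits with a lone array in a group. Background levels were not available, so the limit set by signal over background was not measured.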

Other observations

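The permutation tests of list means and the choice of Saa3 and Mmp3 were made after the results were seen.

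Alas2 and Tent5c had the smallest unadjusted p among the genes at least 0.5 log2 units below untreated in WT and with PE averaged over genotypes, though not in S105A. Alas2 was at 8.89 and 8.58 in WT untreated, 6.53 and 7.11 in WT PE, 8.17 and 8.28 in S105A untreated, and 7.45 and 7.63 in S105A PE; no comparison passed over all genes. The red blood cell list had 4 of 14 genes measured, too few for the list test, and its mean differed by -0.45 between the 4 PE arrays and the 4 untreated arrays (exact permutation test, two-sided, p = 0.0286, the smallest this design can give, adjusted p = 0.132 over 60 tests). The globin genes were among the members with no probe set used here. In the same exact permutation test, the matrix, macrophage, hypertrophy, cell cycle, fibroblast and oxidative phosphorylation lists had this same p and adjusted p. Their PE differences did not pass it when adjusted either. In each of these lists, however, all 4 PE arrays lay beyond all 4 untreated arrays, the most extreme result the test allows. The adjusted value was limited by the number of arrays and tests, so no conclusion about these lists is drawn from it.

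Immediate early genes had 7 of 25 members past the threshold when adjusted over the list alone with PE averaged over genotypes, and 0 over all genes, including Atf3 (0.60), Myc (0.73) and Nr4a1 (0.72). Inflammatory genes had 5 of 22, including Serpina3n (2.07), Il33 (1.16) and Ptgs2 (0.91), and the ERK feedback list 1 of 14, Etv5 (0.97). The 3 lists passed camera with the preset correlation (the inflammatory list not without array 1 or 4, at 0.429 and 0.454), and not otherwise (adjusted p = 0.539, 0.617 and 0.539 with an estimated correlation). Lists of other tissues gave small PE medians that did not pass: lymphocyte markers -0.09, smooth muscle and pericyte markers -0.05, adipocyte markers -0.07, skeletal muscle markers 0.00, atrial muscle markers -0.07 and nerve and glia markers -0.04. Adult sarcomere genes (0.00), glycolysis genes (-0.07), cardiac transcription factor genes (-0.07) and circadian clock genes (-0.10) did not pass either with PE averaged. In WT alone, the cardiac transcription factor list was called lower with PE (median -0.16, preset camera adjusted p = 0.00227, adjusted p = 0.563 with an estimated correlation). Between genotypes, the atrial list mean was 7.091 to 7.198 in the S105A arrays and 6.941 to 7.079 in the WT arrays. This did not pass when adjusted (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.132), again at the smallest p the design can give. With PE, camera with the preset correlation called this list for the genotype effect, a call lost with the filter on low levels and without array 4 or 7. Whether the share of atrial tissue differed is not known. Heat shock genes (median 0.00) and glucocorticoid and muscle atrophy genes (-0.02) did not pass as lists, but Hspa1a (0.90), Hspb1 (0.72) and Hsp90aa1 (0.50) in the one and Mt2 (1.14) in the other passed when adjusted over the list alone, and not over all genes (adjusted p = 0.873 with an estimated correlation for both lists). In S105A alone, the glucocorticoid and muscle atrophy list was called higher with PE (median 0.23, preset camera adjusted p = 0.0134, adjusted p = 0.773 with an estimated correlation). That call was lost with the filter on low levels and without array 3, 4, 5 or 8. Further lists passed with the preset correlation only. Calcium handling genes had a PE median of -0.15 with Adra1b at -0.55 (preset camera adjusted p = 0.00557, adjusted p = 0.539 with an estimated correlation), and unfolded protein response genes one of 0.22 with Pdia4 at 0.60 and Sdf2l1 at 0.50 (preset camera adjusted p = 0.000373, adjusted p = 0.539 with an estimated correlation). Interferon response genes had one of 0.15 (preset camera adjusted p = 0.0162, adjusted p = 0.703 with an estimated correlation), a call lost without array 1, 4, 5 or 7 (0.0885, 0.343, 0.495 and 0.0841) and with the filter on low levels (0.0829). In each of the 3 lists, 0 members passed when adjusted over the list alone or over all genes.

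Saa3 and Mmp3, chosen after their values were seen, were high in array 4 alone. Saa3 was at 6.62 there and between 4.73 and 5.08 in the other 7 arrays, and Mmp3 was at 8.08 against 5.57 to 6.07.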
